A study of Rattus norvegicus with 3 samples.

How the data were processed

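Total RNA of rat testis taken on postnatal days 6, 8 and 10 was labelled with Cy3 and hybridised to 3 one-colour NimbleGen expression arrays, 1 per day. Per the labels' protocols, RNA was extracted with TRIzol and a column kit with DNase treatment, and its quality and amount were read on a spectrophotometer. The labels do not state how many animals contributed to each RNA. Samples were grouped by the collection day in the labels.

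The authors deposited 1 intensity per RefSeq accession and array on a linear scale, made with RMA (background correction, normalization between arrays and summary over probes) per the submitters' processing notes. The RMA version and settings are not given in the sources used here. A second column, named as a standard error per the file headers, has no stated scale, and its values were not used. The deposited series table held the same intensities as the arrays' own files (largest absolute difference 0). RMA draws the intensity distributions of arrays together, so a shift shared by most genes cannot be seen, and its summary over probes hides differences between probes of 1 transcript. Intensities ran from 12.8 to 52817 on day 6, 12.9 to 51331 on day 8 and 13.8 to 54219 on day 10. Signal over background was judged by a random-sequence control, with intensities of 25.0, 24.6 and 25.6, and by the receptor genes. The number of arrays limits the precision.

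Intensities were taken to log2. Accessions without version were matched to the RefSeq gene table of assembly GRCr8, used only for names, genomic spans and no coordinates, since the files name no build. Of 26419 probe sets, 9747 (36.9%) had 1 symbol, 16672 had none and 0 had several. Of 10113 curated (NM) accessions 9618 were named, and of 16306 predicted (XM) accessions 129. An unnamed probe set is unnamed here, not without a gene. Probe sets of the same symbol were averaged on the log2 scale (97 of 9627 named genes had more than 1), and unnamed probe sets were each counted as a gene, giving 26299 genes. Spans in the table cover introns and are not transcript lengths.

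The floor of an array was the higher of its median over all probe sets and the 95th percentile of its olfactory and vomeronasal receptors. The median was the higher on every array (log2 7.78, 7.79 and 7.67; receptor 95th percentile 5.70, 5.60 and 6.11). A gene entered a comparison when above the floor on at least 1 of its 2 arrays, and was counted as changed at 2-fold or more, the threshold of the submitters' design text. Such a fold uses the deposited values. Where a named gene was under the floor on the dimmer array, the text gives the lower bound against that floor. No test across arrays was possible with 1 array per day.

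The 28 gene lists were fixed from textbook markers: undifferentiated spermatogonia, differentiating spermatogonia, pan-germ cell, meiotic prophase, spermatid, Sertoli cell, Leydig cell steroidogenesis, peritubular myoid and smooth muscle, fibroblast and extracellular matrix, endothelial cell, macrophage and immune, mast cell, erythroid, epididymis with mesothelium and rete, adipose tissue, skeletal muscle, nerve and Schwann cell, cell cycle, cholesterol biosynthesis, retinoid metabolism and signalling, cell junctions of the blood-testis barrier, niche growth factors and hormone signalling, imprinted growth network, immediate early and heat shock, piRNA and transposon silencing, ribosomal proteins, oxidative phosphorylation, and olfactory and vomeronasal receptors. A list's median difference over its members above the floor was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. A list was said to stand apart outside the central 95% of them, and needed 3 members. The mast cell list had fewer for day 10 against day 8 and has no value there.

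Genes named in the text followed a rule. It took the 10 largest rises and falls between days 6 and 10 after raising values to the floor, and the 5 largest of each in the other comparisons. It took up to 2 members per list and direction among those 2-fold changed between days 6 and 10, or else the member with the largest difference, and 10 reference markers, of which 7 were matched by name. Symbols that are numbered placeholders and families with near-identical members (receptors, immunoglobulins, ribosomal proteins) were left out of the ranking. The rule gave 89 genes, of which 2 are not reported here, and genes outside it are marked where they appear. The design, floor, lists, naming rule and most alternatives were fixed before the data were examined. The subtraction of the trend with gene span, the matching of random lists on span and the counts over named genes alone were added after seeing the data.

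The trend with span was a lowess fit of the log2 difference on log10 span over named genes (fraction 0.3, 3 iterations). Span-matched random lists used 5 expression bins by 5 span bins among named genes. The 3-day pattern and, as a test added after their values were seen, the counts of genes apart on day 8 were set beside simulations of 3 arrays of unchanged genes (20 draws), with equal noise or with the noise of day 10 raised to the observed spread. Alternatives to the main choices were the series table, median centring, quantile and cyclic loess normalization (limma), the brightest probe set per gene, probe sets counted singly, no floor, a floor at the 75th percentile, both arrays above the floor, values raised to the floor, thresholds of 1.5-fold and 3-fold, unmatched random lists, list means, and lists without genes shared with other lists.

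The steps were tested on simulated data. The spread of the differences between days 8 and 6, any real changes included, was first taken as noise. There, 108 of 13296 unchanged genes passed 2-fold, and 48%, 100% and 100% of 50 genes changed 2-, 3- and 4-fold were called. With the spread between days 10 and 6 taken as noise in the same way, 2909 of 13755 unchanged genes passed. Of the changed genes, 60%, 70% and 90% were called. Of 1000 unchanged lists of 20 genes, 5.9% and 5.4% stood apart in these simulations. Simulated genes were drawn independently, so these shares do not cover lists whose genes move together. Of 100 lists shifted by 0.5, 100% and 78% did, and of 100 shifted by 0.25, 85% and 19%, so a list inside the random lists for day 10 can still hold a shift of that size. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.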

Results

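Gene expression was measured in whole rat testis at 3 ages soon after birth. Testes of Wistar-Imamichi rats, a Wistar stock, were taken on postnatal days 6, 8 and 10, the day of birth being counted as day 1, and total RNA was hybridised to one-colour NimbleGen arrays. At these ages the seminiferous cords hold Sertoli cells and young spermatogonia, and the tissue between the cords holds Leydig, peritubular, endothelial and immune cells. The stated purpose was expression at an early stage of testis development, screened by fold change between days. Each day had 1 array, and each array gave an intensity for 26419 probe sets. The median intensity was 220 on day 6, 221 on day 8 and 203 on day 10. The 1239 olfactory and vomeronasal receptor probe sets, genes mostly outside testis expression although some are known in germ cells, had median log2 intensities of 4.59, 4.58 and 4.67. Across all probe sets, Pearson's r of the log2 intensities was 0.990 between days 8 and 6, 0.967 between days 10 and 6, and 0.966 between days 10 and 8.

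With 1 array per day, no spread between animals or arrays could be estimated, no difference has a replicate check, and no p-value is given. Age, animal and array cannot be told apart, so each difference compares arrays. The number of arrays limits the precision. Within arrays, probe sets of the same gene differed in their log2 change by a median SD of 0.19 for day 10 against day 6 (64 genes), 0.15 for day 8 against day 6 (63 genes) and 0.24 for day 10 against day 8 (65 genes). The pooled SDs over these genes were larger, at 0.40, 0.27 and 0.43. Gene levels are log2 intensities, and differences are log2 of the later over the earlier day. Where a gene lay under the array's floor on the dimmer day, the fold is given as a lower bound against that floor.

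The comparison of day 10 with day 6 covered the whole interval. Star, which carries cholesterol into the mitochondrion for steroid synthesis, was 4.71-fold lower on day 10 (9.55 against 11.78). Plagl1, an imprinted transcription factor, was 5.73-fold lower (11.05 against 13.57), and Cldn1, a tight junction claudin, was 4.63-fold lower (8.97 against 11.18). Tex101, a germ cell surface protein, was 4.07-fold higher (11.52 against 9.50), and Acta1, skeletal muscle actin, was 3.98-fold higher (9.81 against 7.82). Of 13955 genes above the floor on at least 1 of the 2 days, 1196 were at least 2-fold higher on day 10 and 1786 at least 2-fold lower, 21.4% in all. Of the changed genes, 59.9% were lower. With each array centred on its median, the split was 1520 higher and 1506 lower (49.8% lower). That centring moved the median difference of all genes from 0.04 to 0.15 and that of the receptors from 0.088 to 0.20. Quantile and cyclic loess normalization gave 54.8% and 57.4% lower. The size of the excess of lower genes thus depends on the scaling, and the balance is not fixed by these data.

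With values raised to the floor, the largest fall among named genes was that of Agtr2, an angiotensin receptor of fetal and newborn tissues, at least 13.3-fold lower on day 10. Gja5, a connexin of vascular cells, was at least 8.98-fold lower, Car12, a carbonic anhydrase, at least 6.94-fold lower, and Capn6, a calpain-like protein, at least 5.70-fold lower. The kinases Hipk3 and Dstyk were 6.48-fold and 5.81-fold lower, the adhesion molecule Cdh1 (E-cadherin) 5.54-fold, the signalling adaptor Gab2 5.44-fold and the nuclear receptor coactivator Ncoa2 5.24-fold lower. The largest rise was that of Serpina12, an adipokine of the serpin family, at least 6.84-fold higher on day 10 (10.56, under the floor on both earlier days). The serine protease Prss45 was 4.97-fold higher, the interferon-inducible Ifi27l2b at least 4.71-fold, the matricellular protein Ccn5 4.69-fold, Tmem140 4.25-fold and the alcohol dehydrogenase Adh1c 4.06-fold higher. The muscle genes Tnnc2 (fast troponin C) and Mb (myoglobin) were 3.94-fold and at least 3.93-fold higher.

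The size of the difference moved with the genomic span of the gene. Over 5518 named genes, Spearman's rho between the day 10 against day 6 difference and span was -0.43. Of 10 equal groups of genes ordered by span, the shortest (median 2.60 kb) had a median difference of 0.37 and the longest (median 154 kb) -0.50. For day 8 against day 6, rho was -0.15 over 5429 genes. These are relations across genes, which are not independent replicates. Of the named genes, 247 were at least 2-fold higher on day 10 and 644 lower. With the trend subtracted, 227 were higher and 503 lower, and 602 of the 891 genes kept their call. The span-matched percentiles given for the gene groups use random lists with the same spans as well as the same expression.

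**Figure D1:**
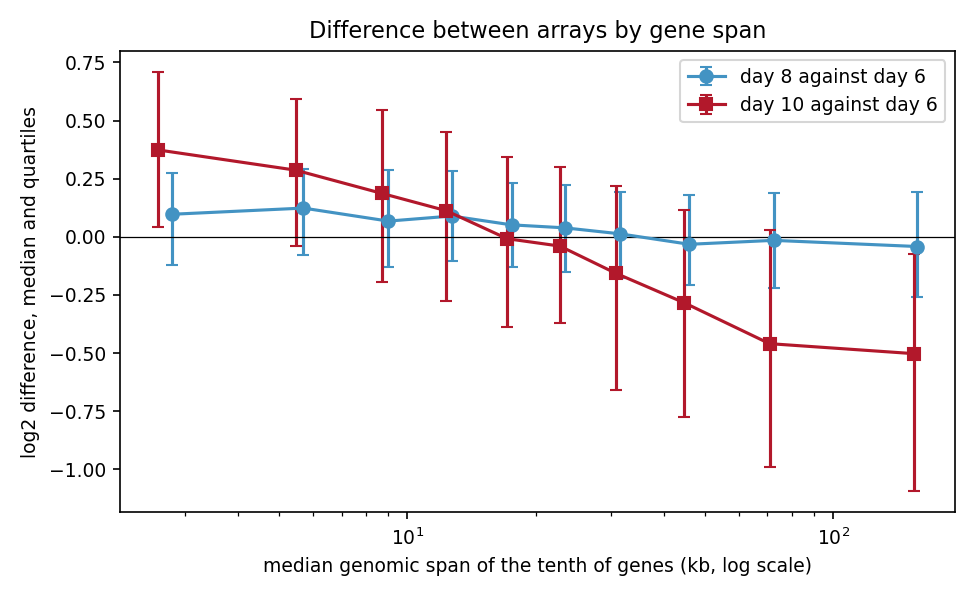
Median log2 difference from day 6 (y axis, bars from the lower to the upper quartile over genes) against the median genomic span of each of 10 equal groups of named genes (x axis, kb, log scale), for the day 8 and the day 10 array. The day 10 medians go from 0.37 at 2.60 kb to -0.50 at 154 kb.

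Of 28 gene lists, 8 had a median difference between days 10 and 6 outside the central 95% of random lists matched on expression. Independent lists of independent genes would give 1.4, but these lists share genes, so the excess over 1.4 has no measured weight. With random lists matched on span as well, 6 stood apart, and 4 did so both ways. The 4 were skeletal muscle and oxidative phosphorylation, higher on day 10, and the imprinted growth network and extracellular matrix, lower on day 10. A percentile describes these arrays, since members of a list are not independent.

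**Figure D2:**
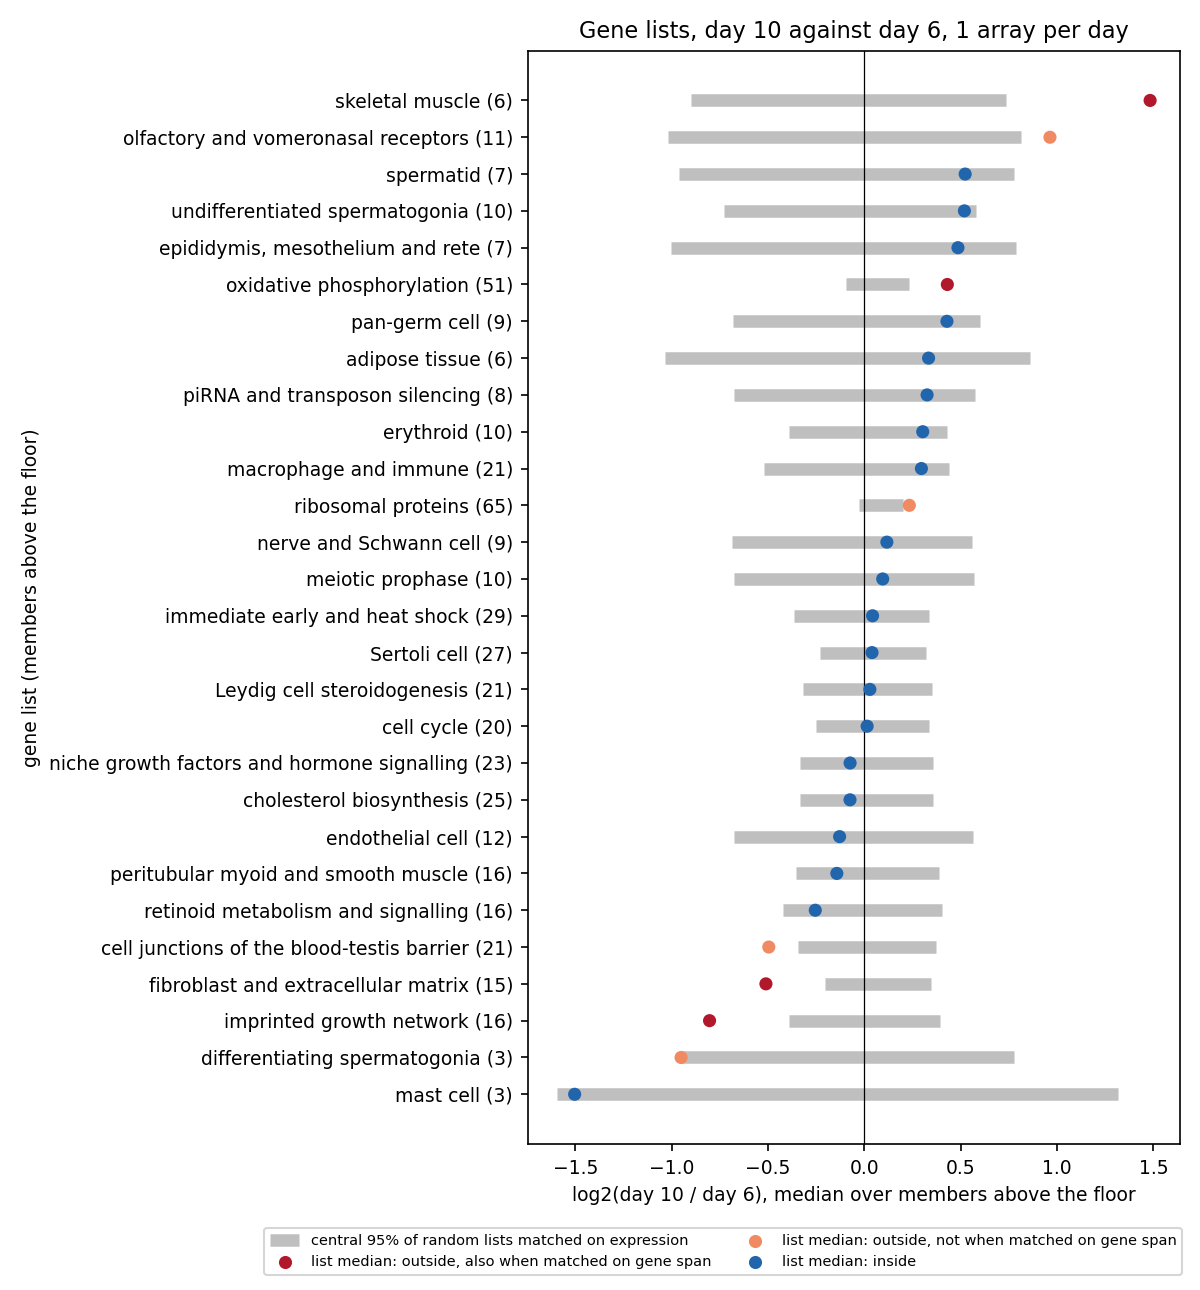
Median log2 difference, day 10 over day 6, of each gene list (points; members above the floor in brackets) with the central 95% of random lists matched on expression (grey bars), 1 array per day. Skeletal muscle (1.48) lies farthest above its bar and the imprinted growth network (-0.80) far below. Undifferentiated spermatogonia and the immediate early and heat shock list lie inside here. Both lie outside random lists of named genes matched on span as well.

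Genes of the imprinted growth network, which regulate fetal and early postnatal growth, were lower on day 10. Of 16 members, all above the floor, 14 had a negative difference, 6 were at least 2-fold lower and 0 at least 2-fold higher. The median was -0.80, at percentile 0.010 of the random lists and 0.090 with span matched (median span 39.4 kb). Besides Plagl1, the amino acid transporter Slc38a4 was 4.61-fold lower. Both were also lower on day 10 than on day 8.

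Extracellular matrix and fibroblast genes were also lower by the list median. Of 15 members, 14 had a negative difference and 3 were at least 2-fold lower (median -0.51, percentile 0.030, span-matched 0.32, median span 21.8 kb). The negative ones include 2 fibrillar collagens that hardly differed, Col1a2 (-0.008) and Col3a1 (-0.08), named after their values were seen. Subtracting the span trend gave them 0.21 and 0.15. Igfbp5, a growth factor binding protein of stromal cells, was at least 3.65-fold lower. The microfibril protein Fbn1 was 2.45-fold lower as measured (-1.29), and -0.76 with the span trend subtracted. Against random lists not matched on expression the percentile was 2.56, just inside.

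Besides Star, the androgen synthesis enzyme Cyp17a1 was 2.35-fold lower on day 10 (12.78 against 14.01), while Vcam1, an adhesion molecule also made by other cells, was 2.54-fold higher. Of 21 Leydig list members above the floor (30 on the array), 1 was at least 2-fold higher and 3 lower, and the median of 0.03 lay inside the random lists (percentile 47.9). Hsd3b1, the next enzyme after side chain cleavage, had 11.23 against 12.33 (-1.10); it was chosen after its values were seen. Cholesterol biosynthesis genes as a list did not stand apart (25 of 26 above the floor, median -0.07, percentile 29.1), with 3 lower and 1 higher. Hmgcs1, which catalyses an early step, was 2.42-fold lower. Idi1, a later enzyme of the pathway, was 2.06-fold higher (1.04, and 0.82 with the span trend subtracted).

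Sertoli cell genes had no common direction. Of 27 members above the floor (32 on the array), 3 were at least 2-fold higher and 5 lower on day 10 (median 0.04, percentile 44.6). Cst12, a cystatin, and Serpina5, a serpin, were 3.00-fold and 2.73-fold higher. The transcription factor Gata4 (-1.32) was more than 2-fold lower, and with the span trend subtracted its difference was -0.93, short of 2-fold. Amh, the hormone that removes the Müllerian ducts, had 11.32 on day 6, 11.15 on day 8 and 10.60 on day 10. Its difference of -0.73 was short of 2-fold as measured and -1.13 with the trend subtracted. Sox9, a further marker fixed in advance, had no name match on the array.

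Junction genes of the blood-testis barrier, which forms between Sertoli cells in the weeks after birth, were lower by the list median on day 10. Of 21 members above the floor (22 on the array), 6 were at least 2-fold lower and 2 higher (median -0.50, percentile 0.36). Their median span was 35.4 kb, and with span matched the percentile was 3.35, inside the random lists. Cldn1 and Cdh1 were the largest falls. Testin, a protein of Sertoli cell junctions, was 2.95-fold higher, and the connexin Gjb2 at least 1.73-fold higher, being under the floor on both earlier days.

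Of 10 undifferentiated spermatogonia genes above the floor (16 on the array), 4 were at least 2-fold higher on day 10 and 1, Cdh1, lower. The median was 0.52, at percentile 95.9 on expression alone and 98.6 with span matched. Ret, the receptor subunit for the niche factor GDNF, was 2.74-fold higher, and the uridine phosphorylase Upp1 2.71-fold higher. Zbtb16, a marker of the same cells, was under the floor on all 3 days (5.66, 5.11 and 5.90). Only 3 differentiating spermatogonia genes were above the floor, of 6 on the array, and all 3 had a negative difference (median -0.95, percentile 2.49, span-matched 12.2, median span 77.3 kb). Kit, the receptor that marks differentiating spermatogonia and also Leydig and mast cells, was 3.16-fold lower (7.93 against 9.59). Stra8, which marks entry into meiosis, had no name match.

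Of 9 pan-germ cell genes above the floor (12 on the array), 2 were at least 2-fold higher and 1 lower (median 0.43, percentile 91.3). Tex19.1, which restrains transposons, was 2.06-fold higher (1.04, and 0.62 with the span trend subtracted). Dnmt3l, which guides DNA methylation in fetal and newborn male germ cells, was at least 3.30-fold lower. Ddx4, the general germ cell marker, differed by 0.15 (11.33 against 11.17). The piRNA and transposon silencing list held 8 genes, all above the floor, 1 of them higher and 1 lower at 2-fold (median 0.33, percentile 85.7). The meiotic prophase list (10 of 19 above the floor) had a median of 0.10 and 2 members at least 2-fold higher. These were Syce1, of the synaptonemal complex, at least 2.57-fold, and Ccnb1ip1, a crossover factor, at least 1.77-fold against the floor. Of 32 spermatid genes on the array, 7 were above the floor (median 0.52, percentile 90.9) and none was 2-fold changed; Tssk3, a testis kinase, had the largest difference (0.78).

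Other somatic lists lay inside the random lists. Peritubular myoid and smooth muscle genes (16 of 18 above the floor) had a median of -0.14, with 1 higher and 3 lower at 2-fold. Acta2, smooth muscle actin, had 15.31, 15.03 and 15.08 on the 3 days. Pln, a regulator of the calcium pump, was at least 3.11-fold higher, Ptch1, the hedgehog receptor, 4.60-fold lower, and Cald1, an actin-binding protein, 2.56-fold lower (-1.35, and -0.83 with the span trend subtracted). Endothelial genes (12 of 16) had a median of -0.13, with 4 lower, among them Eng (2.45-fold) and Clec14a (2.43-fold). Macrophage and immune genes (21 of 28) had a median of 0.30, with 3 higher; the class II gene RT1-Db1 was 2.72-fold higher, and complement C1qb 2.09-fold higher as measured and 0.77 on the log2 scale with the span trend subtracted. Of 12 mast cell genes, 3 were above the floor, Kit among them (median -1.50, percentile 3.14), and Il1rl1 was at least 1.75-fold lower. Erythroid genes (10 of 17) had a median of 0.30, with Rhd 2.37-fold higher and Slc4a1, band 3, at least 1.75-fold lower. Nerve and Schwann cell genes (9 of 19) had a median of 0.12; Gap43, a growth cone protein, was 2.91-fold lower and Ngfr at least 1.41-fold lower.

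Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were higher on day 10. Of 51 members above the floor (54 on the array), 42 had a positive difference, with a median of 0.43 (percentile 100, also with span matched; median span 7.68 kb). The shift was small in each gene, and only Ndufs7, a complex I subunit, passed 2-fold, at 2.27-fold higher (1.19, and 0.96 with the span trend subtracted). Ribosomal protein genes, 60 of 65 with a positive difference, had a median of 0.23 (percentile 99.5). Their median span was 3.25 kb, and the percentile with span matched was 86.8, inside the random lists. None of the 20 cell cycle genes was 2-fold changed (median 0.01, percentile 40.8); Cdca3 had the largest difference (0.81). Mki67 had no name match.

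Niche growth factor and hormone signalling genes (23 of 30 above the floor, median -0.07, percentile 26.9) had 2 higher and 2 lower members. Bmp2 was at least 2.10-fold higher, and Amhr2, the AMH receptor, 2.66-fold higher. Wnt5a was 2.66-fold lower, and Kitlg, the ligand of Kit, at least 1.73-fold lower. Retinoid genes (16 of 24, median -0.25, percentile 9.74) had 4 lower and 1 higher. Aldh1a2, which makes retinoic acid, was 2.71-fold lower, and Crabp2, which carries it to the nucleus, 2.25-fold lower, while Adh1c was the member that was higher. Immediate early and heat shock genes (29 of 32) had 3 higher and 3 lower and a median of 0.04, at percentile 55.8 on expression alone. With span matched (median span 3.80 kb) the percentile was 0.80, so the list lay below other short genes. Ddit3, a stress transcription factor, was 3.10-fold higher and Jund 2.12-fold higher (1.08, and 0.62 with the span trend subtracted). Egr1 was 3.40-fold lower (12.32 against 14.09) and Egr3 at least 1.52-fold lower.

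Of 19 skeletal muscle genes on the array, 6 were above the floor, 5 of these had a positive difference and 3 were at least 2-fold higher, namely Acta1, Tnnc2 and Mb. The median was 1.48 (percentile 99.99, span-matched 99.95), and 0.72 over all 19 without a floor (percentile 99.92). The 11 olfactory and vomeronasal receptors above the floor had a median of 0.96 (percentile 99.0, span-matched 91.0, median span 0.948 kb), with 5 higher and 1 lower at 2-fold. Receptor probe sets above the floor numbered 5, 4 and 10 on days 6, 8 and 10, so most of the 11 entered through day 10. Over all 1239 receptors the median difference was 0.088. Epididymis, mesothelium and rete genes (7 of 19 above the floor, median 0.49, percentile 87.9) had 3 higher and 0 lower; the mesothelial Msln was 2.53-fold higher, and the water channel Aqp1 at least 1.22-fold. Adipose genes (6 of 17, median 0.33, percentile 78.6) had 2 higher and 1 lower. Cfd was at least 1.97-fold higher, Cebpa at least 1.19-fold higher and Lpl at least 1.54-fold lower. With the span trend subtracted, Aqp1, Cfd and Cebpa had 0.97, 0.69 and 0.67, short of 2-fold.

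**Figure D3:**
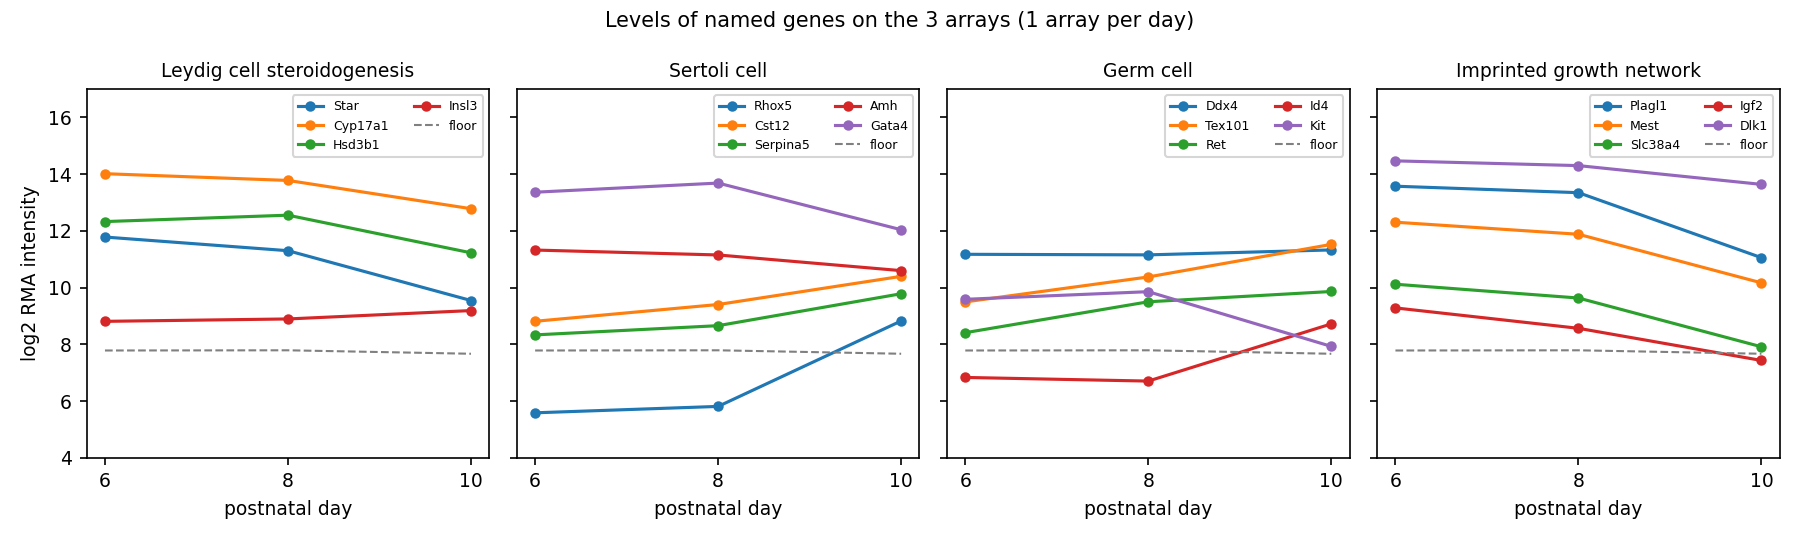
Log2 RMA intensity (y axis) of genes in 4 groups on postnatal days 6, 8 and 10 (x axis), 1 array per day. The floor of each array is a dashed line. The germ cell group mixes genes of the pan-germ cell list and of both spermatogonia lists. All genes drawn were picked after their values were seen. Star goes from 11.78 on day 6 to 11.30 on day 8 and 9.55 on day 10, and Plagl1 from 13.57 to 13.35 and 11.05.

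Day 8 against day 6 was the first step, and it held far fewer changes. Dnmt3l was at least 3.03-fold lower on day 8 (9.39 on day 6, under the floor on day 8). Ptprn, a protein of secretory granules, was at least 3.63-fold lower, the protease inhibitor Slpi 3.24-fold, the angiotensin receptor Agtr1a 2.84-fold and the chemokine Cxcl6 2.82-fold lower. Ccn5 was 2.26-fold higher on day 8, Amhr2 2.21-fold, the DNA polymerase subunit Pold1 2.18-fold, the monooxygenase Fmo5 2.14-fold and Ret 2.13-fold higher. Of 13496 genes above the floor, 70 were at least 2-fold higher and 132 lower, 202 in all. With values under the floor raised to it, 106 genes passed 2-fold.

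Of 28 lists, 6 stood apart in this step, all by small amounts. Sertoli cell genes (median 0.19, percentile 99.0), endothelial genes (0.29, percentile 97.9) and oxidative phosphorylation (0.15, percentile 99.8) were higher on day 8. Meiotic prophase (-0.26 over 8 genes, percentile 1.97), the imprinted growth network (-0.15, percentile 1.78) and the immediate early and heat shock list (-0.13, percentile 1.03) were lower. With span matched, oxidative phosphorylation (97.4) and the imprinted network (2.57) lay inside, and the junction list (0.19, percentile 99.1) and the mast cell list (-0.60, percentile 1.83) lay outside. None of the members of the Sertoli, endothelial and oxidative phosphorylation lists passed 2-fold in this step. The Sertoli and endothelial calls were lost with list means, without a floor and without genes of other lists, and the imprinted call with quantile or loess normalization. With the floor at the 75th percentile, the immediate early median was 0.0044, and the meiotic list had 3 members and a median of 0.16, the other direction.

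Day 10 against day 8 was the second step, with changes about as many as over the whole interval. Ncoa2 was 8.01-fold lower on day 10 than on day 8, Dstyk 6.86-fold, the receptors Notch2 and Ptch1 6.30-fold and 6.08-fold, and Tub at least 6.07-fold lower. Serpina12 was at least 6.81-fold higher, the interleukin antagonist Il1rn at least 5.65-fold, the phospholipase Pla2g2a 2.07 on the log2 scale, and Sln, a calcium pump regulator of muscle, at least 4.15-fold higher. RT1-CE7 was 4.51-fold higher, but this class I gene has near-identical copies, so its value is uncertain. Star was 3.38-fold lower and Kit 3.81-fold lower. Of 13969 genes above the floor, 1196 were at least 2-fold higher and 1920 lower (22.3%; 61.6% of these lower). Median centring gave 1487 higher and 1577 lower (51.5% lower), and quantile and cyclic loess normalization gave 54.7% and 56.4% lower. The totals over the whole interval and over this step were 14.8 and 15.4 times that of the first step. Probe sets of Prlr and of Tpm1, named outside the rule after their values were seen, went in opposite directions by at least 2-fold in this step.

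In this second step 8 of 27 lists stood apart. Pan-germ cell genes were higher by the median (0.58, percentile 98.4), with 8 of 8 positive and 3 at least 2-fold higher, as were skeletal muscle (1.52, percentile 99.99), oxidative phosphorylation (0.25, percentile 99.5), the immediate early and heat shock list (0.35, percentile 99.0) and the receptors (0.91, percentile 98.9). Lower were the imprinted growth network (-0.73, percentile 0.10), extracellular matrix (-0.42, percentile 0.14) and junction genes (-0.54, percentile 0.18). With span matched, the immediate early list (78.4) and the receptors (94.0) lay inside. The immediate early list had a median of -0.07 with the floor at the 75th percentile, and the pan-germ cell call was lost there. The matrix call was lost against unmatched lists. Erythroid genes (0.37, percentile 99.4) and piRNA genes (0.44, percentile 98.8) lay outside with span matched only.

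The 3 days together show how far changes ran in 1 direction. Of the 2982 genes changed between days 6 and 10, 1696 (56.9%, Wilson 95% interval 55.1 to 58.6, counting error over genes only) had a day 8 level between the others. Simulated unchanged genes, with the day 10 spread raised to that observed, gave 64.2%, and with equal noise in the 3 arrays 91.2%. These simulations passed 3565 and 103 genes at 2-fold, so neither matches the 2982 observed. Their noise was normal and alike for all genes. Across 14137 genes, Pearson's r between the first and the second step was -0.28 and the covariance -0.0904. Simulated unchanged genes gave r of -0.21 with the day 10 noise raised and -0.50 with equal noise. The shared day 8 array alone gave a covariance of -0.0706 in simulation. That value follows from the assumption that days 6 and 8 are equally noisy, and a noisier day 8 array would make it more negative. Genes at least 2-fold higher on day 10 than on both earlier days numbered 795, of which 132 had a name, and genes lower than on both numbered 1396, of which 486 had a name. Independent lists of these sizes would share 104 and 222 genes, and simulated unchanged earlier days compared with 1 shared day 10 array would give 1239 and 1234. The counts therefore do not separate a change with age from a departure of the day 10 array alone.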

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

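The matching on gene span, its subtraction and the counts over named genes were chosen after seeing the data. Counts within 1.5 times of the main ones were given by the series table (identical values), the 3 other normalizations, the brightest probe set and single probe sets, in all 3 comparisons, and by no floor and by values raised to the floor in both day 10 comparisons. The floor settings, named genes alone and the thresholds changed which genes could be counted; raising values to the floor and subtracting the span trend changed the differences themselves. For day 10 against day 6 (main 2982) the count was 953 with the floor at the 75th percentile, 1905 above the floor on both arrays, 6156 at 1.5-fold, 978 at 3-fold, 891 among named genes and 730 among these with the span trend subtracted. For day 10 against day 8 (main 3116) the same settings gave 1030, 2017, 6121, 1154, 868 and 707. For day 8 against day 6 (main 202) they gave 32, 87, 1309, 24, 84 and 73, with 765 without a floor and 106 with values raised to the floor. Its share of lower genes was 49.4% at 1.5-fold against 65.3%.

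Of 298 list medians recomputed for day 10 against day 6, 284 kept their side of the limits. These include 28 from the series table, with identical values, and 28 from median centring, which shifts all genes alike. Neither could change sides. Undifferentiated spermatogonia moved outside without a floor (0.46), without genes of other lists (0.86) and with span matched (0.52). Differentiating spermatogonia, 3 genes at the limit, moved inside with the brightest probe set, unmatched lists or span matched (-0.95 each) and without a floor (-0.33). Unmatched lists put the matrix list (-0.51) and ribosomal proteins (0.23) inside and the mast cell list (-1.50) outside. Span matching put junctions (-0.50), ribosomal proteins (0.23) and receptors (0.96) inside and the immediate early list (0.043) outside. It also limited the random lists to named genes, so these moves cannot be credited to span alone. Except for these limits the cause was not tested. Of 586 list medians recomputed in the steps, 534 kept their call, 19 lost it, 29 gained one and 4 reversed. The 55 from the series table could not change, and the step paragraphs name only some of the losses and gains. Reversed for day 8 against day 6 were meiotic prophase (0.16 with the floor at the 75th percentile, 3 genes left, and 0.012 without a floor) and the immediate early list (0.0044 with the floor at the 75th percentile). For day 10 against day 8 it was the immediate early list (-0.075, same floor). Of 581 named differences none reversed. The 97 from the series table were identical values and could not move, and the brightest probe set can move only genes with more than 1 probe set. With the span trend subtracted 12 went under 2-fold and 1, Amh, passed it (-1.13). The share with day 8 between moved to 58.7% with quantile normalization and 59.2% without a floor (range over settings 56.9% to 59.2%). Dim signal limits these data most where changes are few, as in the first step, where 106 of the calls were left once values were raised to the floor. No paired analysis was possible because each day has 1 array, and no array could be left out.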

Other observations

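The genes in this paragraph were chosen after their values were seen, apart from Ptprn, Il1rn, RT1-CE7, Fmo5 and Egr1. Of 13328 genes, 62 (16 named) were at least 2-fold lower on day 8 than on both other days, and 21 (4 named) at least 2-fold higher than on both. Both counts share the single day 8 array. Simulated unchanged genes gave 4.65 and 4.45 with equal noise in the arrays, and 13.8 and 15.1 with the day 10 noise raised, so the second count is close to the latter. The simulated noise was normal and alike for all genes, so heavier noise of the day 8 array is not excluded for either count. In the low group, Il1rn had 9.12, 6.87 and 10.29 on days 6, 8 and 10, the transcription factors Cebpb and Cebpd had 9.86, 8.72 and 9.93 and 9.77, 8.54 and 9.75, and the chemokine Ccl7 had 9.98, 8.81 and 10.02. Ccn1, an early response matricellular gene, had 11.26, 10.12 and 11.84. Other members included Ptprn, Tnnc1, Yipf4 and the class I genes RT1-A3 and RT1-CE7, whose near-identical copies make them uncertain. The named genes highest on day 8 were Fmo5 (10.82, 11.92 and 10.83), Kcns2, Plppr4 and Gpx3. Fos (8.45, 7.13 and 8.99) was also in the low group. Junb (10.62, 9.68 and 10.61) was lowest on day 8 but short of 2-fold, while Egr1 was lower on each later day (14.09, 13.51 and 12.32). Fos, Junb and Egr1 are known to respond within minutes to handling of an animal. The day 8 values of Il1rn, Fos, Ptprn and RT1-A3 were under the floor of that array (7.79), so the depth of their dip is uncertain. With 1 array per day these differences have no replicate check.

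For the patterns weighed here, the tests of dim probe sets, of muscle tissue and of Leydig cell share were chosen after the result was seen. The first pattern is the excess of changes on the day 10 array, 891 named genes against 84 on the day 8 array, both against day 6. With the span trend subtracted the counts were 730 and 73, a ratio of 10.0, so the trend is not the whole cause, although genomic span only partly stands for transcript length or probe distance from the 3' end. Under 3 other normalizations the day 10 count was 892 to 896, and the lowest ratio, with 894 genes against 85, was 10.5. The deposited values were already normalized between arrays, so rescaling them could change little. The result argues only against a remaining difference in scale, and the normalization within RMA was not tested. In the 1346 brightest named genes the SD of the day 10 difference was 1.84 times that of day 8 (bootstrap interval 1.74 to 1.96). The interval resamples genes and holds no spread between arrays. Of these genes, 52 passed 2-fold on day 10 and 1 on day 8, so most of the 891 calls lie in dimmer genes. The larger spread in bright genes argues against noise of dim probe sets as the whole cause, but their share of the calls stays open. An effect of age, a different animal, and the RNA quality or hybridisation of the day 10 array stay open as untested, since each day has 1 array.

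The second pattern is the higher skeletal muscle list on day 10, whose median, matched on span and expression, lay at percentile 99.95 of random lists, so short span alone is not the cause. Muscle tissue carried along with the day 10 testes may contribute. All 19 members without a floor had a median of 0.72 (percentile 99.92) and 14 were higher, but 13 of the 19 were not above the floor on day 10. From day 6 to day 10, Ckm went from 5.52 to 7.17, Myl11 from 5.84 to 7.35, Myl1 from 5.09 to 5.31, Tnni2 from 5.65 to 6.04 and Myh3 from 5.71 to 5.48, all under the floor, Tnnt1 from 9.56 to 9.27, and outside the list Tnnt2 from 10.94 to 12.58 and Sln from 8.54 to 9.84 (genes chosen after their values were seen). The criterion set for muscle tissue asked for a median above the random lists, which was met. It also asked for more than 14 members to be higher, which was narrowly missed. Many members were also near or under the floor. Muscle tissue and expression within the testis therefore cannot be told apart here, and no member is in another list.

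The third pattern is the lower Star, Cyp17a1 and Hsd3b1 on day 10. With the span trend subtracted the 3 differences ran from -2.55 to -1.37, so the trend is not the cause. A smaller share of Leydig cells is a possible explanation: Cyp11a1, Hsd17b3 and Scarb1, 3 of 4 further genes enriched in these cells, were lower by at least 0.5, and the median of the 4 was -0.78. The remaining one, Insl3, was higher (0.38, range of the 4 from -0.93 to 0.38), so the criterion set, all 4 lower by at least 0.5, was missed. With the span trend subtracted Insl3 had -0.06, Scarb1 -0.47, Cyp11a1 -0.84 and Hsd17b3 -0.75. The whole Leydig list had a median of 0.03, with 11 of 21 members positive and 10 negative. The positive ones include Vcam1 (1.35) and, named after their values were seen, Tspo (0.82) and Hsd11b1 (0.48). A change of regulation within Leydig cells with age stays open and cannot be told apart from a change in their share in these whole-testis arrays.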
